A study of Mus musculus with 8 samples.

How the data were processed

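RNA from ascending aorta of 10-week-old male mice on a C57BL/6J background was hybridised to 8 Affymetrix Clariom D mouse arrays, 4 from Fbn1mgR/mgR and 4 from wild-type mice, per the labels. Groups were taken from the genotype label and array names from the sample titles. The 2 genotypes share 0 replicate numbers.

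The values used were log2 signals per transcript cluster as deposited by the authors, already normalized. The submitters' processing notes name the Transcriptome Analysis Console without a version, and the normalization method and the summary of probes are not given in the sources used here. The deposited values are rounded to 2 decimals and reach at most 19.93, and 137 transcript clusters lie within 1 log2 unit of that ceiling, where differences are compressed. No detection p-values were used here. The median of 1083 olfactory receptor genes, 3.38, with a 95th percentile of 4.13, served as a reference for dim signals; 6.1% of the tested clusters lay at or below that percentile. In 38 called clusters the lower genotype mean did, and the size of such differences is uncertain. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.151.

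Of 65956 transcript clusters, 30604 carried 1 gene symbol in the platform annotation, 2146 carried several and 33206 carried none. Gene IDs of 22818 clusters matched the RefSeq gene table of assembly GRCm38.p6, which updated 827 symbols and was otherwise used only for which genes neighbour each other. No gene was named from a cluster with several symbols. The brightest cluster stood for a gene with several.

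Clusters above the median of the mean signals (4.01) were tested, which left 32957, of which 18122 carried 1 symbol, 1299 several and 13536 none. Differences are Fbn1mgR/mgR minus wild-type on the log2 scale, tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) and Benjamini-Hochberg adjustment, with a threshold of 0.05. All adjusted p-values of genes come from limma. Before the data were examined, 43 gene lists were fixed, and the 41 with at least 5 tested members were tested with camera from limma (preset correlation of 0.01), with camera using an estimated correlation, and with fry. The exact two-sided permutation test of list means over 70 labellings was chosen after the results were seen. Files were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

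The rule for named genes, fixed before the data were examined, took the 12 largest rises and the 12 largest falls among clusters with 1 symbol past the threshold whose genotypes did not overlap, leaving out predicted or unnamed gene models and gene segments. It also took a panel of 20 genes, of which 17 had a cluster with 1 symbol; Fbn1 and Spp1 were not analysed here, and 1 gene is not reported here. For gene lists, up to 4 members with the smallest p are given.

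Alternatives fixed before the data were examined included eBayes without a trend, robust eBayes, array weights, no filter and only clusters above the upper quartile of mean signal. Others fixed beforehand were only clusters with 1 symbol, quantile normalization, median centring, a tissue marker mean as a covariate, other thresholds and each array left out. That covariate was the marker list of other tissues that varied most over the arrays among 7, which the data showed to be brown fat. A covariate for the lower quartile of each array and a fit without both arrays highest in brown fat markers were added after the data were seen. The limma fit was tested on simulated data for this comparison with 65956 clusters, of which 32978 were tested. It called 72% of 100 clusters changed by 1 log2 unit and 95% of 100 changed by 2, with 0 wrong signs, and 16 unchanged clusters (8.7% of calls). At most 1 cluster was called in each of 5 simulations without changes. In simulated lists, 5% of 200 unshifted lists had an unadjusted camera p under 0.05 with the preset correlation. The simulated genes varied independently of each other. Members of the real lists did not, with estimated correlations up to 0.816 (B cell markers), so this rate does not carry over to them.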

Results

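RNA from the ascending aorta of 10-week-old male mice was measured on 8 whole-transcriptome arrays, 4 from mice homozygous for the mgR allele of Fbn1 (Fbn1mgR/mgR; arrays mgR611, mgR612, mgR613 and mgR614) and 4 from wild-type mice (arrays WT675, WT676, WT742 and WT744). Fbn1 encodes fibrillin-1, the main protein of extracellular microfibrils, and mgR is a hypomorphic allele used to model severe Marfan syndrome with aortic aneurysm. Each array gave log2 signals for 65956 transcript clusters, with a median between 3.95 and 4.07 per array and a highest value of 19.93. Pearson correlations across transcript clusters were 0.989 to 0.993 within the mutant arrays (6 pairs), 0.989 to 0.992 within the wild-type arrays (6 pairs) and 0.985 to 0.990 between genotypes (16 pairs). The number of arrays limits the precision of every value. The labels do not say that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical. Fbn1 itself was not analysed here, so the genotype labels were not checked against the transcript of the mutated gene.

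The comparison asked which transcripts differ between the Fbn1mgR/mgR and the wild-type ascending aorta. In the mutant aorta, 9 of 23 cytokine and chemokine genes, 7 of 12 complement genes, 5 of 13 genes of modulated smooth muscle and 4 of 20 matrix proteases rose (camera adjusted p = 0.147 for each of these lists with an estimated correlation). Of 22 macrophage markers tested, 19 rose (camera adjusted p = 0.0755 with an estimated correlation) and 0 fell (0 lower at an unadjusted p under 0.05 in limma). Their mean signal was 9.54 ± 0.273 in the mutant against 7.70 ± 0.123 in the wild-type arrays (log2, SD, n = 4 each). The clock gene Arntl rose while 6 genes of the opposite phase fell. None of 22 contractile smooth muscle genes passed the limma threshold in either direction, with 7 lower and 1 higher at an unadjusted p under 0.05.

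Of 32957 transcript clusters tested with limma, 507 were higher and 184 were lower in Fbn1mgR/mgR at an adjusted p under 0.05, and 320 and 84 of these differed by at least 2-fold. Among the 507 that were higher, 402 carried a single gene symbol, 33 carried several and 72 carried none. Among the 184 that were lower, the numbers were 102, 4 and 78. In all 691 called clusters the values of one genotype lay entirely above those of the other; this held for 8.92% of all tested clusters, where chance gives 2.86%. Leaving out mgR613 or mgR614, or WT675, WT676, WT742 or WT744, gave 311, 319, 273, 283, 313 and 272 higher clusters. The number of lower clusters was 115, 96, 105, 89, 122 and 67 without mgR611, mgR613 and mgR614 and WT675, WT676 and WT744.

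Ccl8, which encodes a chemokine that attracts monocytes, had the largest rise among the named genes, by 4.66 (SE 0.308, adjusted p = 0.000405), from 7.24 ± 0.279 to 11.9 ± 0.666 (log2, SD, n = 4 each), or 25.2-fold. Igfbp2, an insulin-like growth factor binding protein, rose by 4.59 (SE 0.585, adjusted p = 0.00509) and Bcl2a1a, of the BCL2 family of survival factors, by 3.89 (SE 0.358, adjusted p = 0.00117). The class II histocompatibility genes H2-Eb1 and H2-Ab1 rose by 3.71 (SE 0.310, adjusted p = 0.000823) and 3.39 (SE 0.333, adjusted p = 0.00152). Ccr2, the receptor of monocyte chemokines, rose by 3.50 (SE 0.333, adjusted p = 0.00135). Prg4, which encodes lubricin, rose by 3.51 (SE 0.418, adjusted p = 0.00378). Serpina3n, a serine protease inhibitor, rose by 3.65 (SE 0.616, adjusted p = 0.0188), but missed the threshold without WT675, WT676 or WT744, at adjusted p = 0.0615, 0.0567 and 0.0527 (0.00535 to 0.0615 over all alternatives). The other rises among the 12 largest were in Clec4b1 (3.21), Lyz1 (3.12), Ear-ps2 (3.08) and Ly86 (3.01), with adjusted p from 0.00288 to 0.0123. Bcl2a1a, Lyz1 and Ear-ps2 have near-identical relatives, and the class II genes have related family members. Their probes may therefore share signal, and the values of single members are uncertain.

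The fall in Tcap was the largest among the named genes, at -4.26 (SE 0.579, adjusted p = 0.00635), from 11.6 ± 0.619 in wild-type to 7.30 ± 1.29 in Fbn1mgR/mgR arrays (log2, SD, n = 4 each); Tcap encodes telethonin, a titin-binding protein of striated muscle. Wif1, which encodes a secreted inhibitor of Wnt signalling, fell by 2.47 (SE 0.146, adjusted p = 0.000336), and Kcnj15, a potassium channel gene, fell by 2.47 (SE 0.187, adjusted p = 0.000602). The complement component C7 fell by 2.51 (SE 0.305, adjusted p = 0.00400). Omd, which encodes the small leucine-rich proteoglycan osteomodulin, fell by 2.33 (SE 0.348, adjusted p = 0.0103). Klk10, Fibin, the desmosome gene Dsp and Angptl7 had log2 differences of -2.16, -2.14, -2.14 and -2.02, with adjusted p from 0.00285 to 0.00635. Olfr224, annotated as an olfactory receptor, fell by 2.63 (SE 0.402, adjusted p = 0.0115). Cybrd1, an iron-regulated reductase gene, fell by 2.89 (SE 0.588, adjusted p = 0.0397). Its adjusted p was 0.0805, 0.0516, 0.105, 0.0997, 0.117, 0.0955 and 0.117 without mgR611, mgR612, mgR613, mgR614, WT675, WT676 and WT744 in turn, and ranged from 0.00681 to 0.191 over all alternatives. Lrrc17 had a difference of -2.32 (SE 0.473, adjusted p = 0.0405) and missed the threshold without any 1 of the arrays except mgR612, with adjusted p between 0.0600 and 0.120.

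**Figure D1:**
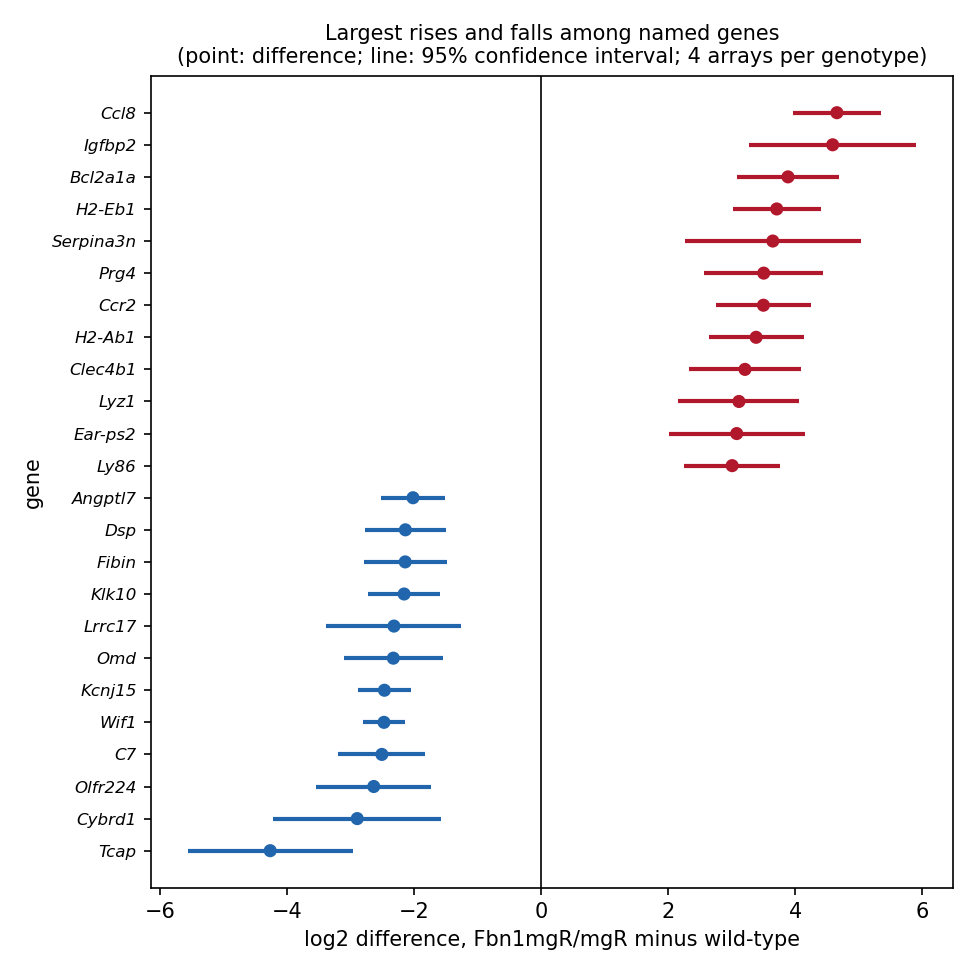
Log2 difference between Fbn1mgR/mgR and wild-type arrays (x axis) for the 12 named genes with the largest rises (red) and the 12 with the largest falls (blue), with lines for 95% confidence intervals (4 arrays per genotype). Differences run from 4.66 for Ccl8 to -4.26 for Tcap, and no interval includes 0.

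The 19 macrophage markers that rose included Mpeg1 (2.59, adjusted p = 0.000519), the integrin Itgam (2.05, adjusted p = 0.00103), the lysosomal protein gene Cd68 (2.40, adjusted p = 0.00117) and the signalling adaptor Tyrobp (2.94, adjusted p = 0.00135). The remaining 3 did not pass, Folr2 at 1.80, Cd163 at 0.71 and Gpnmb at 0.32. Of 23 cytokine and chemokine genes, 9 rose and none fell by limma (1 was lower at an unadjusted p under 0.05), and the 4 with the smallest p were Ccl8, Ccl6 (2.96, adjusted p = 0.00143), Ccl9 (2.81, adjusted p = 0.00352) and Il1rn (1.32, adjusted p = 0.00507), the last an antagonist of the interleukin-1 receptor. Of 12 complement genes, 7 rose, among them the receptor C3ar1 (2.24, adjusted p = 0.00132), C1qb (2.62, adjusted p = 0.00141), C1qa (1.63, adjusted p = 0.00358) and properdin, Cfp (1.83, adjusted p = 0.0142). C1qa, C1qb and C1qc were also on the macrophage list. C7, a complement gene outside this list, fell by 2.51 (adjusted p = 0.00400). Complement members that rose numbered 4 without mgR613 or WT675, WT742 or WT744. Adjusted over the list alone, 21 macrophage markers, 17 cytokine genes and 10 complement genes were higher.

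The median differences of these 3 lists were 1.81 for macrophage markers (camera adjusted p = 1.32e-27; adjusted p = 0.0755 with an estimated correlation), 0.96 for cytokines and chemokines (camera adjusted p = 2.04e-12; adjusted p = 0.147 with an estimated correlation) and 1.32 for complement (camera adjusted p = 1.18e-08; adjusted p = 0.147 with an estimated correlation). In all 3 lists the mean of every mutant array lay above that of every wild-type array (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 arrays can give; adjusted p = 0.0837 over 41 lists).

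**Figure D2:**
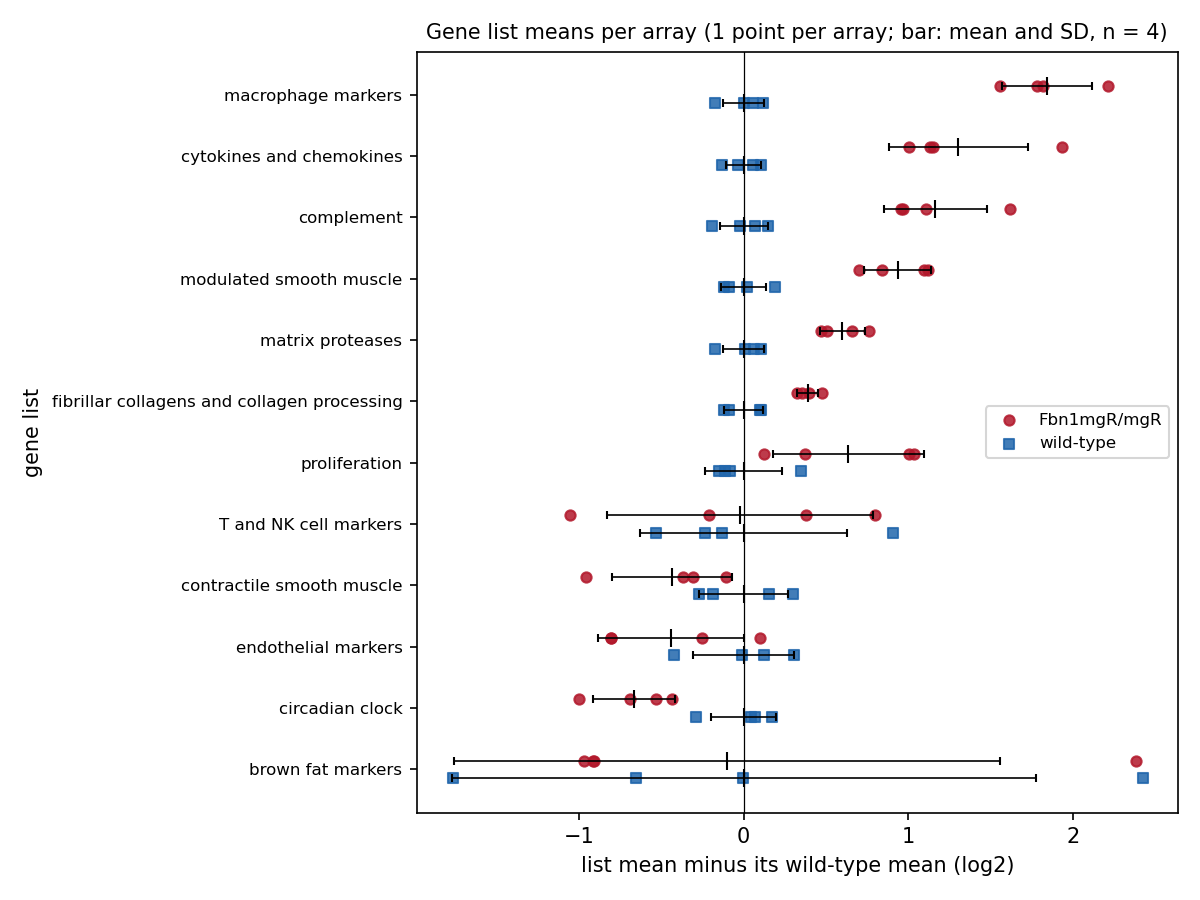
Mean log2 signal of the tested members of 12 gene lists in each array, minus the list's wild-type mean (x axis), with red circles for the 4 Fbn1mgR/mgR and blue squares for the 4 wild-type arrays, and bars for mean and SD. The genotypes do not overlap for macrophage markers, cytokines, complement, modulated smooth muscle, matrix proteases, collagens and clock genes, while the brown fat mean is 10.9 in mgR614 and 11.0 in WT676 (log2) and at most 8.54 in the other 6 arrays.

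Other leukocyte lists had fewer changed members or none. No B cell marker passed among 7 (5 were higher at an unadjusted p under 0.05), while 2 were higher when adjusted over the list alone; the median was 0.48 (camera adjusted p = 0.00192; adjusted p = 0.567 with an estimated correlation). Of 89 immunoglobulin variable segments, 2 rose, Igkv4-60 (0.45) and Igkv4-70 (0.79), with wild-type means of 3.79 and 4.02 in the range of dim signals. In that list 16 were higher when adjusted over the list alone (median 0.30, camera adjusted p = 1.26e-07; adjusted p = 0.330 with an estimated correlation). The number that rose was 9 without mgR614, 1 without mgR611 or WT676, WT742 or WT744, and 0 without mgR612. None of 10 neutrophil markers passed in limma, and 0 had an unadjusted p under 0.05 (median 0.35, camera adjusted p = 0.0491; adjusted p = 0.719 with an estimated correlation). The neutrophil list call was lost without mgR611, mgR613, WT675, WT676 or WT744, with camera adjusted p from 0.104 to 0.321. Without mgR612 the camera adjusted p was 0.00581. Over all arrays and each array left out, the neutrophil median ranged from 0.22 to 0.50. T and NK cell markers had a median of -0.045 and a mean of -0.022 while camera ranked them upward (adjusted p = 0.617), and 0 of 11 passed limma (3 higher at an unadjusted p under 0.05). The direction of that list turned on single arrays, with a median of 0.35 without mgR612 (camera adjusted p = 0.0902), 0.335 without WT744 (0.0973), 0.066 without mgR611 and -0.26 without mgR613. Its camera adjusted p was 0.0902 to 0.963 over the fits with the preset correlation and 0.922 with an estimated correlation. Thymocyte markers (8 tested, median -0.15, camera adjusted p = 0.521) and mast cell markers (7 tested, median 0.59, camera adjusted p = 0.203) had no member past the limma threshold, with 0 and 1 at an unadjusted p under 0.05. The thymocyte median was 0.071 without mgR612, 0.056 without WT744 and -0.36 without mgR613. The mast cell list was called higher without mgR613 (median 0.85, camera adjusted p = 0.00271, 1 member past the threshold), while its median was 0.24 without mgR612 and 0.26 without WT742. For that list the camera adjusted p was 0.00271 to 0.778 over the fits with the preset correlation and 0.922 with an estimated correlation. Among 14 interferon response genes, Oas1a rose by 1.29 (adjusted p = 0.0180) and Mx1 (0.26), Usp18 (0.78) and Irf7 (0.43) did not pass. Of all members, 3 were higher when adjusted over the list alone (median 0.22, camera adjusted p = 0.0160; adjusted p = 0.719 with an estimated correlation). The interferon list call was lost without mgR612, WT676, WT742 or WT744, with camera adjusted p from 0.0504 to 0.0997. Oas1a missed the threshold without mgR613 (adjusted p = 0.0572) or WT676 (0.0543) or WT744 (0.0612), and its adjusted p ranged from 0.0114 to 0.115 over all alternatives.

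Among matrix genes, the matrix proteases held 4 that rose and none that fell of 20 (1 was lower at an unadjusted p under 0.05): Ctss, the cysteine protease cathepsin S (2.99, SE 0.189, adjusted p = 0.000336), Mmp12, macrophage elastase (2.28, SE 0.275, adjusted p = 0.00385), Mmp19 (0.84, adjusted p = 0.0120) and Mmp13 (0.92, adjusted p = 0.0185). Mmp13 missed the threshold without mgR614 or WT675, WT742 or WT744, with adjusted p from 0.0510 to 0.0529. Adjusted over the list alone, 7 proteases were higher and 1 was lower (median 0.41, camera adjusted p = 4.67e-05; adjusted p = 0.147 with an estimated correlation). Of 26 collagen and collagen processing genes, Col12a1 (2.34, adjusted p = 0.00141) and Col1a1 (0.98, adjusted p = 0.00837) rose, P4ha3 (0.44, adjusted p = 0.0656) and Col8a1 (1.28, adjusted p = 0.114) did not pass. P4ha3 passed without mgR612 (0.52, adjusted p = 0.0329; 0.0327 to 0.256 over all alternatives). Of the collagen list, 5 were higher when adjusted over the list alone (median 0.27, camera adjusted p = 3.09e-05; adjusted p = 0.177 with an estimated correlation). Thbs1 (2.45, adjusted p = 0.00522), Fn1 (1.98, adjusted p = 0.00701), Tnc (2.67, adjusted p = 0.00713) and Mgp (0.63, adjusted p = 0.0101), which encode thrombospondin-1, fibronectin, tenascin-C and matrix Gla protein, rose among 19 proteoglycan and matricellular genes. Signals of Mgp were 18.5 to 19.5, near the highest value in the data, where differences are compressed. The proteoglycan and matricellular list had a median of 0.14 to 0.22 over all arrays and each array left out. That list had 7 higher and 2 lower adjusted over the list alone (median 0.22, camera adjusted p = 0.0708; 0.0306 without WT742, 0.0346 without WT744 and 0.0254 to 0.158 over the fits with the preset correlation; adjusted p = 0.526 with an estimated correlation), and 2 of its members passed as lower without mgR612 or mgR614.

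Of 20 elastic fibre and microfibril genes, Mfap4, which encodes a microfibril-associated protein, fell by 1.21 (adjusted p = 0.0209), while Eln (1.10, adjusted p = 0.0536), Lox (1.14, adjusted p = 0.0789) and Ltbp4 (-1.14, adjusted p = 0.120) did not pass. Adjusted over the list alone, 4 were higher and 3 were lower, with a median of -0.051, a mean of 0.000 and a downward camera rank (adjusted p = 0.695). Without mgR612, whose Eln signal was 13.5 against 14.3 to 14.4 in the other mutant arrays, Eln (1.32, adjusted p = 0.0145) and Lox (1.37, adjusted p = 0.0316) passed and Mfap4 did not (adjusted p = 0.0545). Over all alternatives the adjusted p ranged from 0.0145 to 0.223 for Eln and from 0.0204 to 0.330 for Lox. Mfap4 also missed the threshold without mgR614 (0.0559) or WT675 (0.0648), WT742 (0.0601) or WT744 (0.0718), and over all alternatives its adjusted p was 0.00970 to 0.0720. Timp1, an inhibitor of metalloproteinases, rose by 1.94 (adjusted p = 0.00713) among 7 protease inhibitors, a list with a median of -0.015, a mean of 0.20 and an upward camera rank (adjusted p = 0.885). Basement membrane genes had a median of 0.00, a mean of 0.019 and a downward camera rank (adjusted p = 0.617), with 0 of 15 past the limma threshold and 3 higher and 3 lower at an unadjusted p under 0.05.

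Smooth muscle genes were described by 2 lists. Contractile genes had a median difference of -0.44 (camera adjusted p = 0.000150; adjusted p = 0.719 with an estimated correlation), with none past the threshold over all genes and 3 lower when adjusted over the list alone. Without mgR614 the contractile median was -0.21 (camera adjusted p = 0.00441; 1.16e-06 to 0.00951 over the fits with the preset correlation). The smallest p values belonged to Rgs5 (-0.98, adjusted p = 0.0656), Itga8 (-1.05, adjusted p = 0.114), Pgm5 (-0.69, adjusted p = 0.116) and Des (-0.81, adjusted p = 0.166). Rgs5, a regulator of G protein signalling, passed without mgR614 (-1.15, adjusted p = 0.0404; 0.0214 to 0.170 over all alternatives). With the brown fat mean as a covariate, Rgs5 (-0.95, adjusted p = 0.0214) and the integrin gene Itga8 (-1.07, adjusted p = 0.0452; 0.0452 to 0.257 over all alternatives) both passed. The array mgR614 had the lowest contractile mean, at 10.8 against 11.4 to 11.7 in the other mutant and 11.5 to 12.1 in the wild-type arrays. Of 13 genes of modulated smooth muscle, 5 rose, with Igfbp2 (4.59), Tnfrsf11b, the decoy receptor osteoprotegerin (1.52, adjusted p = 0.00522), Tnc (2.67) and Timp1 (1.94) having the smallest p; Tnc and Timp1 are also counted on the matrix lists. The median was 0.51 (camera adjusted p = 0.000590; adjusted p = 0.147 with an estimated correlation) and 0.33 without mgR614, and 5 were higher when adjusted over the list alone. Integrin and focal adhesion genes (20 tested) had 0 past the limma threshold, with 2 higher and 1 lower at an unadjusted p under 0.05, and a median of 0.015 (camera adjusted p = 0.995).

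Among genes of the preset panel not described with a list, the transforming growth factor genes Tgfb1 (0.34, adjusted p = 0.578) and Tgfb2 (0.47, adjusted p = 0.596) did not pass, nor did Mmp2 (0.40, adjusted p = 0.688), Hif1a (0.45, adjusted p = 0.179), Agtr1a (0.11, adjusted p = 0.824) and Nox4 (-0.43, adjusted p = 0.366). Il1b, which encodes interleukin-1 beta, was at 1.70 (adjusted p = 0.0522) and passed without mgR612 (1.99, adjusted p = 0.0255; 0.0255 to 0.139 over all alternatives). Ccl2, a monocyte chemokine, rose by 2.43 (SE 0.349, adjusted p = 0.00837). Myh11, smooth muscle myosin, was at -1.01 (adjusted p = 0.226), and Acta2, smooth muscle actin, at -0.12 (adjusted p = 0.605) with signals of 19.4 ± 0.172 and 19.5 ± 0.0390 (log2, SD, n = 4 each), close to the highest value in the data. Fbn2 and Mmp9 lay below the intensity filter and were not tested, and Spp1 was not analysed here.

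Endothelial markers had a median of -0.42 (camera adjusted p = 0.00711; adjusted p = 0.719 with an estimated correlation). It was -0.20 without mgR611, -0.23 without mgR614 and -0.19 without both mgR614 and WT676, where the list call was lost (camera adjusted p = 0.0612; 0.000135 to 0.0612 over the fits with the preset correlation). The transcription factor gene Erg fell by 1.21 (adjusted p = 0.0447), while Nos3 (-1.04, adjusted p = 0.0922), Pecam1 (-0.91, adjusted p = 0.174) and Tek (-0.95, adjusted p = 0.313) did not pass, and 2 of 15 were lower when adjusted over the list alone. Without mgR613, Nos3 (-1.27, adjusted p = 0.0352; 0.0352 to 0.310 over all alternatives) and Pecam1 (-1.18, adjusted p = 0.0442; 0.0442 to 0.380) passed. The Erg call was lost without any 1 of the arrays except mgR612, with adjusted p from 0.0546 to 0.122. Fibroblast markers had 0 of 13 past the limma threshold (1 higher and 2 lower at an unadjusted p under 0.05, and as many adjusted over the list alone; median -0.052, camera adjusted p = 0.540). Mesothelial markers had a median of -0.55 (8 tested, camera adjusted p = 0.0653), with 0 past the limma threshold and 2 lower at an unadjusted p under 0.05. The mesothelial list was called lower without mgR612 (-0.83, camera adjusted p = 0.0127), mgR614 (-0.57, 0.0381) or WT742 (-0.94, 0.000903), while its median was -0.34 without WT675 and -0.35 without mgR613 or WT676. For that list the camera adjusted p was 0.000903 to 0.387 over the fits with the preset correlation and 0.842 with an estimated correlation. Of 10 cartilage markers, the proteoglycan gene Acan (2.03, adjusted p = 0.00439) and Comp (0.89, adjusted p = 0.0397) rose and Chad (-0.70, adjusted p = 0.146) and Hapln1 (-0.29, adjusted p = 0.206) did not pass. Of all members, 2 were higher and 2 lower when adjusted over the list alone (median 0.011, camera adjusted p = 0.617). Comp missed the threshold without mgR611, mgR613 or mgR614 or WT675, WT676 or WT744, with adjusted p from 0.0846 to 0.121.

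Markers of neighbouring tissues varied between arrays within each genotype. Brown fat markers were at 10.9 in mgR614 and 11.0 in WT676, and between 6.78 and 8.54 in the other 6 arrays, and white adipocyte markers were at 9.35 and 9.65 in these same arrays and between 7.24 and 8.32 in the others. Between genotypes the medians were -0.004 for brown fat (8 tested, camera adjusted p = 0.617) and -0.28 for adipocyte markers (11 tested, camera adjusted p = 0.456), with 0 past the limma threshold and 0 and 1 at an unadjusted p under 0.05. Without mgR614 both lists were called lower, brown fat at -1.08 (camera adjusted p = 0.0260; 0.0260 to 0.985 over the fits with the preset correlation) and adipocyte markers at -0.78 (0.0163; 0.0163 to 0.777). With an estimated correlation the adjusted p was 0.922 for both lists with all arrays. Without WT676 their medians were 0.90 and 0.26. With the brown fat mean as a covariate, 484 clusters were higher and 217 lower. Without both of these arrays, an alternative chosen after seeing the data, 172 were higher and 77 lower. In that fit, with 3 arrays per genotype, the members that rose numbered 13 of the macrophage, 7 of the cytokine, 3 of the complement, 2 of the matrix protease, 3 of the modulated smooth muscle, 2 of the collagen, 1 of the proteoglycan and 1 of the cartilage list. Among the largest changes, Serpina3n (adjusted p = 0.0516), Lyz1 (0.0590), Ear-ps2 (0.0758), Olfr224 (0.0847), Cybrd1 (0.191) and Lrrc17 (0.149) missed the threshold there. Their differences in that fit were 2.85, 3.21, 3.28, -2.37, -2.59 and -1.84 in turn. All 691 clusters called with all arrays kept their sign there. This was certain beforehand, because their genotypes do not overlap, so it is no support for the calls. Cardiomyocyte markers (10 tested, median -0.14, camera adjusted p = 0.617) had 0 past the limma threshold and 0 at an unadjusted p under 0.05. Among 7 skeletal muscle markers Actn3 fell by 0.71 (adjusted p = 0.0227), and the median was -0.095 (camera adjusted p = 0.0424; adjusted p = 0.298 with an estimated correlation). That list call was lost without mgR612, mgR613, WT675 or WT742, with camera adjusted p from 0.0774 to 0.162. The Actn3 call held only without mgR612 or mgR613 among the fits that left out 1 array. Schwann cell and neuron markers (4 tested) and erythroid markers (2 tested) had too few members for a list test, and 0 of them had an unadjusted p under 0.05 in limma.

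The circadian clock list had 1 gene that rose and 6 that fell of 14. Arntl, the clock activator also called Bmal1, rose by 2.69 (SE 0.275, adjusted p = 0.00181). The transcription factor genes Hlf and Tef fell by 1.97 (SE 0.285, adjusted p = 0.00866) and 1.61 (SE 0.258, adjusted p = 0.0145), and the clock repressor Per2 fell by 1.51 (SE 0.245, adjusted p = 0.0158). Per3, Nr1d2 and Dbp also fell, by 1.22, 1.63 and 1.61. Adjusted over the list alone, 3 were higher and 10 were lower (median -1.27, mean -0.66, camera adjusted p = 0.000180; adjusted p = 0.240 with an estimated correlation). Arntl passed whichever array was left out. The members that fell numbered 3 without mgR611, mgR612 or mgR614 or WT675, WT676 or WT744, and 0 without both arrays high in brown fat markers, where Hlf was at -1.84 (adjusted p = 0.0900; 0.00220 to 0.0900 over all alternatives).

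**Figure D3:**
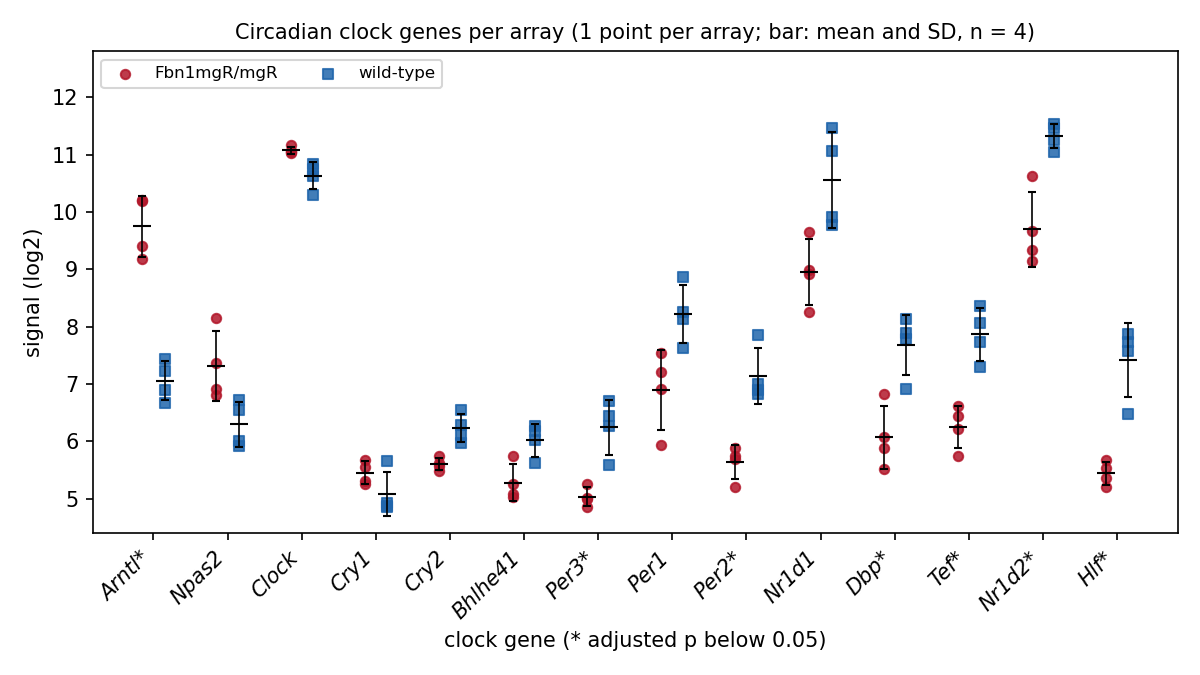
Log2 signal (y axis) of the 14 tested clock genes (x axis) in each array, with red circles for the 4 Fbn1mgR/mgR and blue squares for the 4 wild-type arrays, bars for mean and SD, and asterisks for adjusted p below 0.05. Arntl lies higher in all 4 mutant arrays, with a difference of 2.69, and the 6 marked genes other than Arntl lie lower in all 4.

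Proliferation genes had a median of 0.56 (camera adjusted p = 1.44e-07; adjusted p = 0.526 with an estimated correlation). None of 18 passed the limma threshold over all genes, 12 were higher at an unadjusted p under 0.05 and 9 when adjusted over the list alone, with Kif20a (0.60, adjusted p = 0.0806), Aurkb (0.45, adjusted p = 0.111), Cdk1 (1.08, adjusted p = 0.111) and Plk1 (0.74, adjusted p = 0.139) having the smallest p. Without mgR611, 4 genes of the list passed, among them Cdk1 (1.32, adjusted p = 0.0411; 0.0411 to 0.351 over all alternatives) and Plk1 (0.93, adjusted p = 0.0384; 0.0384 to 0.435) but neither Kif20a nor Aurkb. Of 18 oxidative stress genes, the NADPH oxidase subunits Ncf4 (0.79, adjusted p = 0.00187) and Cybb (2.12, adjusted p = 0.00674), which are found in phagocytes, rose, and Ncf1 (0.48, adjusted p = 0.0656) and Hmox1 (0.40, adjusted p = 0.196) did not pass. Of all members, 3 were higher when adjusted over the list alone (median 0.29, camera adjusted p = 0.0121; adjusted p = 0.147 with an estimated correlation). Without mgR611 the oxidative stress list call was lost (camera adjusted p = 0.0512; 0.00211 to 0.382 over the fits with the preset correlation). Of 12 ER stress genes, Sdf2l1 rose by 1.70 (adjusted p = 0.0331), and Creld2 (1.53, adjusted p = 0.0534), Herpud1 (-0.89, adjusted p = 0.0543) and Hsp90b1 (0.44, adjusted p = 0.145) did not pass. Creld2 passed without mgR611 (adjusted p = 0.0441) or WT744 (0.0116), with 0.0116 to 0.251 over all alternatives. Herpud1 passed without mgR613 (0.0268), with 0.0268 to 0.204. In this list 4 were higher and 1 lower when adjusted over the list alone (median 0.44, camera adjusted p = 0.167). The ER stress list was called higher without WT744 (0.47, camera adjusted p = 0.00749; 0.00749 to 0.317 over the fits with the preset correlation; adjusted p = 0.847 with all arrays and an estimated correlation), and its median was 0.28 without mgR614. Sdf2l1 missed the threshold without any 1 of the arrays except mgR611, with adjusted p from 0.0592 to 0.0997.

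Signalling and metabolic lists were not called in either direction by camera with all arrays. A mixed fry test, which counts changes in either direction, gave unadjusted p = 0.000415 for TGF-beta genes and 0.175 to 0.745 for the other lists here. Among lists described above that camera did not call, its p ranged from 3.07e-06 (proteoglycans and matricellular proteins) to 0.831 (thymocyte markers). It was 8.2e-05 for basement membrane and 0.000312 for ER stress genes, so a small value is not particular to TGF-beta genes. Among 20 genes of TGF-beta signalling 1 rose, Thbs1 (median 0.19, camera adjusted p = 0.671), with 3 higher and 3 lower at an unadjusted p under 0.05. The median was 0.070 without WT675, 0.087 without mgR613 and 0.12 without WT676. Without mgR612 the receptor gene Tgfbr3, named after its values were seen, passed as lower (-0.999). Renin-angiotensin genes (8 tested, median 0.009, camera adjusted p = 0.870), hypoxia and glycolysis genes (20 tested, median 0.006, camera adjusted p = 0.987), targets of miR-122 known from liver (10 tested, median 0.010, camera adjusted p = 0.656) and ribosomal protein genes (39 tested, median -0.015, mean 0.000, camera adjusted p = 0.617) had 0 past the limma threshold, with 1, 3, 1 and 2 higher at an unadjusted p under 0.05. Immediate early genes, which respond within minutes to tissue handling, had a median of 0.005, a mean of -0.11 and an upward camera rank (17 tested, adjusted p = 0.987), with 0 past the limma threshold and 1 higher and 1 lower at an unadjusted p under 0.05. Respiratory chain genes (77 tested) had a median of -0.025 (camera adjusted p = 0.540), with 0 past the limma threshold and 0 at an unadjusted p under 0.05. Their direction turned on single arrays, with a median of 0.17 without WT676 (camera adjusted p = 0.0435), -0.16 without mgR614 (0.00145) and -0.14 without WT742 (0.0118). The camera adjusted p ranged from 0.00145 to 0.924 over the fits with the preset correlation and was 0.951 with an estimated correlation. The arrays WT676 and mgR614 are those highest in brown fat markers.

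Of 46 snoRNA genes, whose products guide RNA modification, 4 rose and none fell in limma (1 was lower at an unadjusted p under 0.05): Snora75 (1.40, adjusted p = 0.00543), Snora69 (1.19, adjusted p = 0.0188), Snord49b (1.53, adjusted p = 0.0371) and Snord42a (1.42, adjusted p = 0.0450). The wild-type mean of Snora75 was 4.10, in the range of dim signals, so that its difference is uncertain in size. Adjusted over the list alone 8 were higher (median 0.30, camera adjusted p = 0.000245; adjusted p = 0.147 with an estimated correlation), and the number that rose was 1 or 2 without any 1 of the arrays except mgR612. None of 309 microRNA genes passed limma, with 4 higher and 18 lower at an unadjusted p under 0.05 (median -0.025, camera adjusted p = 0.197). Leaving out mgR611 or mgR613 let 1 microRNA gene pass as higher. The microRNA list was called lower without mgR611 (-0.057), mgR614 (-0.046) or WT676 (-0.026), with camera adjusted p of 0.00194, 0.0449 and 0.0224 (0.00194 to 0.777 over the fits with the preset correlation; adjusted p = 0.922 with all arrays and an estimated correlation). Of 80 olfactory receptor genes above the filter, 5 fell, Olfr330 (-1.95, adjusted p = 0.00502), Olfr224, Olfr329 (-1.29, adjusted p = 0.0218), Olfr328 (-1.27, adjusted p = 0.0438) and Olfr331, and as many when adjusted over the list alone (median -0.070, camera adjusted p = 0.00567; adjusted p = 0.719 with an estimated correlation). The number that fell was 3 without mgR611 and 2 without mgR612, mgR613 or mgR614 or WT676, WT742 or WT744. The olfactory median was -0.020 without WT742 and -0.114 without mgR611. The olfactory list call was lost without mgR612, mgR613 or WT742, with camera adjusted p of 0.0619, 0.183 and 0.276 (4.84e-06 to 0.276 over the fits with the preset correlation). Across the 41 lists tested, camera with a preset correlation put 13 higher and 5 lower, fry 9 and 2, and camera with an estimated correlation 0 in either direction, where 8 had an unadjusted p under 0.05. Of the 23 lists that the preset correlation did not call, 17 had medians on both sides of 0 over all arrays and each array left out. None of the 18 called lists did. Calls and medians come from the same arrays, so this contrast is not separate support for the calls.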

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

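The tests of collection times, of thymus or lymph node, of perivascular fat, of smooth muscle cells and of macrophage number against RNA per cell were chosen only after the results were seen.

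In 18 of 338 groups of 4 arrays, 1 array stood far from the other 3, where chance flags about 1 in 20 groups (16.9 here). Of these, 5 were in mgR614 and 4 in WT744. Among the mutant arrays, Eln was at 13.47 in mgR612 (14.33 to 14.39 in the others), Ccl2 at 9.75 in mgR614 (8.02 to 8.29), Mmp9 at 3.66 in mgR611 (3.86 in the others) and Acta2 at 19.14 in mgR614 (19.47 to 19.49). Herpud1 was at 11.67 in mgR613 (10.98 to 11.07) and Atp8b4 at 5.52 in mgR613 (5.67 to 5.70). In mgR614 the list means stood apart at 12.985 for proteoglycans (13.324 to 13.361), 7.899 for cytokines (6.970 to 7.119) and 10.928 for brown fat markers (7.577 to 7.641).

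Among the wild-type arrays, Klk10 was at 8.29 in WT675 (7.40 to 7.54), Olfr329 at 5.90 in WT675 (6.65 to 6.75), Angptl7 at 9.33 in WT676 (9.93 to 9.96) and Acta2 at 19.57 in WT742 (19.49 to 19.50). In WT744, Hsp90b1 was at 16.05 (15.66 to 15.69), Plk1 at 5.84 (5.25 to 5.35), Cry1 at 5.65 (4.85 to 4.93) and the proliferation list at 5.957 (5.463 to 5.528). The neutrophil list was at 5.372 in WT742 (4.304 to 4.422).

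For the count of called clusters, 1 of 35 splits of the arrays, the real one, gave as many as 691, and the highest other split gave 13. The real split stood far apart, but a share of 1 of 35 is the smallest that this test can give. The test alone therefore does not exclude chance, and it cannot separate genotype from any other difference that follows the same split. For the number of lists called by camera, chance cannot be excluded, since 7 of 35 splits gave as many as the real 18 and the highest other gave 27.

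The rise of macrophage markers in Fbn1mgR/mgR was set against other tissue in the dissection. Thymus or lymph node would raise T and NK cell and thymocyte markers as much, but the macrophage median lay at least 1.293 above theirs with all arrays and with each left out (spread 0.757). B cell markers (median 0.482) and immunoglobulin variable segments (median 0.297) were not part of this comparison, so it does not cover tissue rich in B cells. Fewer smooth muscle cells would raise every other cell type alike, but the gap to endothelial and fibroblast markers was at least 1.738 in the same fits (spread 0.757). Perivascular fat would raise fat markers as much. However, the macrophage median lay at least 0.967 above those of brown fat and adipocyte markers in these fits (spread 0.757). This spread is the largest SD over genes within the lists compared, not the variation between arrays. Array means of brown fat markers had SDs of 1.66 (mutant) and 1.77 (wild-type), so the gaps alone do not exclude other tissue. Of the arrays highest in brown fat, mgR614 (9.48) lay below mgR612 (9.91) and mgR613 (9.515) and above mgR611 (9.25) in macrophage markers. WT676 (7.75) lay below WT744 (7.81) and above WT675 (7.70) and WT742 (7.53). In brown fat markers WT676 (10.97) was followed by WT744 (8.54), WT675 (7.89) and WT742 (6.78), nearly the same order. Within the wild-type arrays a part played by fat therefore stays open. Whether the mutant aorta held more macrophages or more RNA of these genes per macrophage cannot be told apart, since 0 of the measures count cells.

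The clock genes moved in opposite directions, and a shift of clock phase is a candidate explanation. Among 7 clock genes other than those that changed (5 of them on the clock list), 3 are known to peak with Arntl and 4 have the opposite phase. The median of the 3 lay 1.246 above that of the 4, although 0 of the 7 passed limma. These 7 were chosen once the clock calls were known. Since 5 of them belong to the clock list, the gap is not separate support for a phase shift. For a glucocorticoid difference between the mice, both parts of the bar set beforehand were missed, a median of 0.5 in size (-0.468 over 9 response genes) and 2 passing genes (1, Cdkn1a, which rose by 1.90, adjusted p = 0.0116). By the rule set beforehand, missing both parts counts against a glucocorticoid difference. It stays open here only through a condition outside that rule, because the SD of 0.845 over these response genes reaches past the bar. This SD is not the uncertainty of the median, which lay close to the bar. Collection of the genotypes at different times of day stays open as well, with times given for 0 of 8 arrays, and so does an effect of genotype on the clock.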

How the results depend on the processing

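The covariate for the lower quartile of the array and the fit without both arrays highest in brown fat markers (mgR614 and WT676) were chosen after the data were seen. No paired analysis was possible because the genotypes share 0 replicate numbers. Leaving out 1 array gave 272 (without WT744) to 521 (without mgR611) higher and 67 (without WT744) to 146 (without WT742) lower clusters. Between 328 and 497 of the 691 calls were shared with these fits. Without both arrays highest in brown fat markers, 172 were higher and 77 lower, with 232 shared. Fits with fewer arrays have less power, and no other cause was tested. No filter gave 339 higher and 99 lower. An adjusted p under 0.10 gave 816 and 393, and an adjusted p under 0.05 with at least 2-fold gave 320 and 84. Camera called 3 lists lower without mgR613 and 10 without mgR614, and 8 higher among clusters above the upper quartile of mean signal, where fewer genes were tested. Camera with an estimated correlation called 0 lists higher and 0 lower (8 at an unadjusted p under 0.05), and fry called 9 higher and 2 lower. The respiratory chain median ranged from -0.163 without mgR614 to 0.172 without WT676 (camera adjusted p = 0.0435, with 0.00145 to 0.924 over the fits with the preset correlation), a reversal whose cause was not tested directly. With both of these arrays left out the median was 0.027 (camera adjusted p = 0.905). With the brown fat mean as a covariate it was 0.008 (camera adjusted p = 0.924). Of the named genes' results, 861 with 1 array left out stayed on their side of the threshold, 133 were lost, 12 gained and 0 reversed. Under the other alternatives, the numbers were 1144, 66, 25 and 0. Genes whose genotypes do not overlap cannot reverse when arrays are left out. For lists called in neither fit, only the signs of medians with each array left out were compared. Robust eBayes and the restriction to 1 symbol were not run on lists. Signals near the ceiling of 19.93 and the 6.1% of tested clusters at or below the 95th percentile of olfactory receptor genes limit what can be read from single values.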

Other observations

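The set of class II genes, the genes named with it, the neighbours of the olfactory receptors and the test of the genes closest to Fbn1 were chosen only after the results were seen.

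Of 10 tested genes of antigen presentation by class II molecules, 7 were higher in Fbn1mgR/mgR by limma, with a median of 1.98 over the set, among them H2-DMb1 (2.99, adjusted p = 0.000657), H2-Aa (2.30) and H2-DMb2 (2.15, adjusted p = 0.00218); H2-Eb2 (0.24), H2-Oa (0.30) and H2-Ob (0.66) did not pass, and no enrichment of the set was tested. Clec9a, a receptor known from dendritic cells, rose by 1.78 (SE 0.135, adjusted p = 0.000602) and the integrin Itgax by 1.89 (SE 0.172, adjusted p = 0.00117). Class II genes belong to a family of related genes, among them H2-DMb1 and H2-DMb2. Whether their probes share signal was not tested, so single values are uncertain.

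The 5 olfactory receptor genes that fell, Olfr224 and Olfr328 to Olfr331, neighbour each other on chromosome 11 in assembly GRCm38.p6. The gene 2210407C18Rik in the same stretch fell by 1.25 (SE 0.245, adjusted p = 0.0346) but missed the threshold without mgR611, mgR612, mgR614, WT675, WT742 or WT744 (adjusted p = 0.0637 to 0.106). Olfr30 differed by 0.025 (adjusted p = 0.965). Whether the probes of these related receptors share signal was not tested, so the 5 falls may not be separate changes.

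Among clusters without a gene symbol, TC1400000459.mm.1 rose by 5.26 (SE 0.559, adjusted p = 0.00220) and TC0200001502.mm.1 fell by 3.10 (SE 0.246).

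Genes beside Fbn1 were examined because a targeted allele may carry donor strain alleles or a construct that alter its neighbours. A wide stretch was not rich in calls: the 200 nearest tested genes held 8, where the median window held 6. Closer in, 5 of the 20 nearest were called, all higher, namely Gatm (2.26), Fgf7 (0.83), Atp8b4 (0.82) and the paralogs Slc28a2 (0.60) and Slc28a2b (0.51). Taking any of 5 window sizes, 2.86% of all genes as centre had neighbours as rich in calls. With 1 array left out, 3 or 4 of the 20 nearest were called and the share was 2.53% to 8.28%, with 7.37% without mgR611 and 8.28% without mgR612. Slc28a2 was called in none of these 8 fits and Slc28a2b only without mgR613. An effect of the allele or its donor DNA on the closest genes therefore stays open, as does regulation of these genes in the diseased aorta.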
